A study of Mus musculus with 24 samples.

How the data were processed

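Total RNA of mammary glands was extracted with Trizol, labelled with biotin in a one-cycle protocol and hybridized to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The table holds 1 value for each of 45101 probe sets on each of 24 arrays. The deposited values are linear intensity values, as their range shows (lowest 3.38, the same on all 24 arrays). The software that summarized the probes and the normalization between arrays are not given in the sources used here, although near-equal medians show that some scaling was done. The labels call the arrays of a group biological replicates, and each is a pool of 5 mice. A p-value here measures the spread between such pools, not between single mice. The number of arrays, 3 per group, limits the precision.

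Values below the 10th percentile of the table (7.38) were set to it and log2 was taken. The log2 medians of the arrays spanned 0.16, under the limit of 0.3 that had been set for a further normalization, so that the values were used as deposited. The 64 control probe sets were left out of the tests. Genes were named through the platform annotation of 2016, in which 34958 probe sets have 1 gene symbol, 932 several and 9160 none. Probe sets with several or no symbols were not used for genes. A probe set had to lie above the median of its array on at least 3 of the 24 arrays, and a gene was read from its probe set with the highest mean, which left 12352 genes. Values under the array median lie close to background, where a fold change is imprecise and the floor makes it too small. Gene positions were not used here.

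All 24 arrays were fitted in 1 linear model with a mean per group with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 16 residual degrees of freedom and an intensity trend in the variance. Contrasts gave progesterone minus oil at each time, the mean of the 4 differences, a moderated F-test of whether the differences differ between times, and one of the 4 oil groups. Benjamini-Hochberg adjustment ran over all genes, and a gene was called at an adjusted p under 0.05. Errors of intensities are SD over 3 arrays, and errors of log2 fold changes are SE from the model. Tests are two-sided. The calls were tested on data simulated for these 12352 genes from their means and residual spread with normal noise, at 3 arrays per group. There, 41.8% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2 were called for the 76 h comparison, where 6.06% of the calls were unchanged genes. For the 4 h comparison 43.3%, 91.0% and 100% were called, with 8.24% of the calls unchanged genes. The simulated noise was independent between genes and held no deviating array, so that these shares may not hold for the real calls.

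Of 26 gene lists, 25 had at least 3 tested members. The red blood cell list had 2 and was not tested. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 100 pairs of list and time, beside camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance. Against the oil arrays of other times the lists were tested with the preset correlation only. Overlaps of calls were tested with Fisher's exact test. The ratio of control probes at the 3' and 5' ends was compared with exact permutation tests.

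The grouping, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per time, the 10 largest rises and 10 largest falls among called genes whose 3 arrays per group do not overlap, up to 4 called members of each list, and 11 genes always, of which 9 were measured and the others are not analysed here. For the F-tests it takes the 10 smallest p. For any list the rule takes the members with the largest absolute change, and the largest rises and falls leave out symbols that are only clone or model names. Genes named beyond this rule (Tceal9 and the clock genes Dbp, Npas2, Per2, Per3 and Nr1d1) were chosen after their values had been seen. Genes always named stand in the text whatever their values. The alternatives were no filter or one at the 60th percentile, quantile normalization, centring on array medians, a floor at the 25th percentile, a pseudocount of 16, the mean of a gene's probe sets or each probe set alone, the variance without trend or robust, array weights, other thresholds, a fit to the 6 arrays of a time, a replicate block, other set tests and leaving out each array in turn. Other oil arrays as controls, a skeletal muscle score as covariate, leaving out 28 or 76 h, and the overlap without single arrays were added after the data had been examined.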

Results

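Gene expression was measured in the mammary glands of ovariectomized, nulliparous BALB/c mice given progesterone or its vehicle, sesame oil. Ovariectomy at 6 weeks of age removes the ovarian source of the hormone, and 2 weeks of rest followed. Mice then received 1 mg of progesterone in 100 µl of oil, or oil alone, as a daily injection under the skin, and were killed 4, 16, 28 or 76 h after the first injection. On a daily schedule the 28 h and 76 h mice would have received more than 1 injection. Time after the first injection therefore cannot be told apart from the number of injections and the hours since the last. The 8 groups hold 3 arrays each, 24 in all, and each array carried the pooled RNA of 5 mice, so that a group stands for 15 mice. The array was the Affymetrix Mouse Genome 430 2.0, on which a gene is read by 1 or more sets of short probes. The median intensity per array lay between 62.8 and 70.2, and within groups the log2 values of 2 arrays correlated with r from 0.973 to 0.989 across genes. The series asks what the progesterone receptor does to gene expression in this tissue, and every time has its own oil arrays for the comparison. Of 12352 genes tested, 23 changed at 4 h, 38 at 16 h, 313 at 28 h and 2195 at 76 h with limma at an adjusted p under 0.05.

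**Figure D1:**
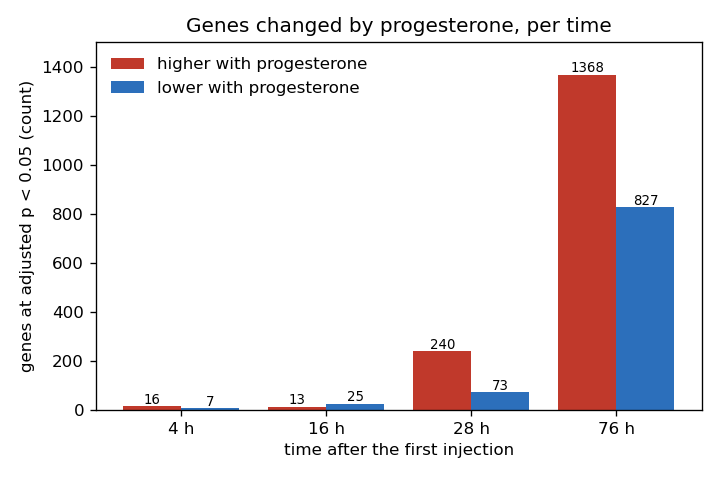
Number of genes called per time (limma, adjusted p under 0.05, 3 arrays per group), split into genes higher (red) and lower (blue) with progesterone, against the time after the first injection. The bars reach 16 and 7 genes at 4 h, 13 and 25 at 16 h, 240 and 73 at 28 h, and 1368 and 827 at 76 h.

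At 4 h, the transcript of the progesterone receptor itself, Pgr, fell from an intensity of 464 ± 46.6 in oil to 85.5 ± 15.6 with progesterone (mean ± SD, n = 3 arrays each), a log2 fold change of -2.45 ± 0.21 (SE) with an adjusted p of 2.02e-07. The largest rise was that of Aldh3a1, an aldehyde dehydrogenase, from 32.9 ± 9.94 to 457 ± 108, or 14.1-fold (adjusted p = 3.22e-08). In oil Aldh3a1 lay under the array median, where a fold change is imprecise. The glycosyltransferase B3gnt7 rose by 3.11 on the log2 scale, the adhesion molecule Cntnap2 by 2.96, the fibrinogen gamma chain Fgg by 2.26, the acyl-CoA thioesterase Acot1 by 1.96 and the lysophospholipid acyltransferase Mboat1 by 1.66. Smaller rises were those of Ppp1r1b (1.57), an inhibitor of protein phosphatase 1, Depdc7 (1.40), Wfdc12 (1.31) and the keratin-binding protein Eppk1 (1.11). Besides Pgr, 6 genes fell. These were Ly6d (-1.17), the cationic amino acid transporter Slc7a2 (-1.02), the sodium, potassium and chloride cotransporter Slc12a2 (from 2660 ± 115 to 1330 ± 145), Tpgs1 (-0.68), the LIM-domain protein Lmo4 (-0.51) and the autophagy receptor Sqstm1 (-0.46). In all, 16 genes rose and 7 fell. The split was 22 to 5 with quantile normalization and 15 to 10 with arrays centred on their medians.

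Of the 18 measured members of a list of progesterone-responsive mammary genes, drawn from the literature on this tissue, Pgr alone was called at 4 h over all genes, while 3 rose and 3 fell when adjusted over the list alone. Wnt4, a WNT ligand made by hormone-sensing cells, had intensities of 78.6 ± 12.7 and 156 ± 14.4 and an adjusted p of 0.0688. Id4 (0.44), Tnfsf11 (0.12), Elf5 (-0.29), Ccnd1 (-0.26) and Esr1 (0.21) did not pass the test, nor did the beta-casein gene Csn2 (0.03). Among 21 steroid response genes, the metallothionein Mt2 rose from 723 ± 57.0 to 1380 ± 111 over all genes, 2 rose and 1 fell when adjusted over the list alone, and Fkbp5 stood at 0.11. Lower as lists, by camera, were the lymphocyte markers (median -0.27, adjusted p = 6.89e-06, and adjusted p = 0.406 with an estimated correlation, with 4 down when adjusted over the list alone), fatty acid and triglyceride synthesis (-0.12, 0.0078, and adjusted p = 0.741 with an estimated correlation) and the white adipocyte markers (-0.07, 0.0343, and adjusted p = 0.704 with an estimated correlation). The circadian clock list was lower too (-0.33, 0.0343, and adjusted p = 0.358 with an estimated correlation), with 2 members up and 7 down when adjusted over the list alone. The EGF-family and WNT list was higher (0.10, 0.0343, and adjusted p = 0.255 with an estimated correlation). Skeletal muscle markers were also lower (median -0.51, adjusted p = 0.0078, and adjusted p = 0.849 with an estimated correlation). Against the oil arrays of the other times, those of 28 h among them, the lymphocyte list stayed lower (-0.35, adjusted p = 6.99e-07). Fatty acid synthesis (0.10, 0.112), the white adipocyte (-0.00213, 0.894), clock (-0.02, 0.783) and muscle markers (0.04, 0.943) and the EGF-family and WNT list (0.13, 0.0693) were not called there. On the 4 h arrays the 3' to 5' log2 ratio of the actin control probes, a sign of RNA length, was 0.557 ± 0.0448 with progesterone and 0.425 ± 0.0151 in oil (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). That of the Gapdh probes was 0.199 ± 0.177 against -0.0787 ± 0.104 (exact permutation p = 0.2).

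The 4 h count rested on single arrays. It was 477 without progesterone replicate 3, 12 without progesterone replicate 1 or oil replicate 2, 14 without progesterone replicate 2 and 35 without oil 16 h replicate 3. Of the 18 genes named as called, 11 kept the call without any one of the 6 arrays of that time. The other 7 (Depdc7, Wfdc12, Slc7a2, Tpgs1, Lmo4, Sqstm1 and Mt2) lost it in part, 7 of them without oil replicate 2 or progesterone replicate 1, 6 without oil replicate 1 or progesterone replicate 2 and 5 without oil replicate 3, at adjusted p up to 0.421.

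At 16 h, progesterone raised Wnt4 and 3 of 20 markers of the basal, or myoepithelial, layer of the mammary duct, and lowered Pgr, Upk3a and Tspan1, among others. The basal keratin gene Krt17 rose from 26.9 ± 7.11, under the array median, to 115 ± 19.0, a log2 change of 2.11 ± 0.40 (adjusted p = 0.0167), and Krt5 rose by 0.70. Wnt4 rose from 88.8 ± 9.64 to 223 ± 15.8 (2.52-fold, adjusted p = 0.00484). Further rises were those of the T-type calcium channel Cacna1g (1.27), the ubiquitin ligase Rnf180 (1.26), Ppp1r1b (1.12), Mboat1 (1.02), the transcription factor Tfap2b (0.78), Eppk1 (0.73) and podocalyxin, Podxl (0.64). Pgr was again lower, at 170 ± 19.9 against 465 ± 107 (-1.44 ± 0.21, adjusted p = 0.00119). The largest falls were those of the uroplakin Upk3a (-2.28) and the tetraspanin Tspan1 (-2.16), followed by Clca3a2 (-1.88) and Clca3a1 (-1.24), near-identical relatives whose probes may not tell them apart. Ccn2, a secreted matrix-associated factor, fell by 1.30, Ly6d by 1.23, the chaperone Dnajc12 by 1.19 (log2 -1.19), Slc7a2 by 1.16 and Tlcd4 by 1.09. Another probe set of Mboat1 read -0.34 and another of Tlcd4 0.20 at 16 h, neither of them called.

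By list, 3 of 20 basal markers rose over all genes (Krt17, Krt5 and smooth muscle actin, Acta2, by 0.29), 7 rose and 1 fell when adjusted over the list alone, and the list was higher as a whole (median 0.15, adjusted p = 0.000143, and adjusted p = 0.19 with an estimated correlation). Among the 21 steroid response genes, Ddit4 (-0.84), Tsc22d3 (-0.72) and Dusp1 (-0.65), known targets of glucocorticoids, fell over all genes, against 2 up and 6 down when adjusted over the list alone. The list as a whole was not called (adjusted p = 0.268). Of the 18 progesterone-responsive genes, Wnt4 rose and Pgr fell over all genes, with 2 up and 4 down when adjusted over the list alone. Id4 (0.55), Elf5 (-0.60), Tnfsf11 (-0.26), Ccnd1 (0.14), Esr1 (0.09), Csn2 (-0.27) and Fkbp5 (-0.16) did not pass. The mitosis list was lower (median -0.44, adjusted p = 0.000592, and adjusted p = 0.741 with an estimated correlation), with none of its 35 members called, and so was the replication list (-0.25, 0.0343, and adjusted p = 0.782 with an estimated correlation). Lymphocyte markers (-0.30, 0.00355, and adjusted p = 0.708 with an estimated correlation) and skeletal muscle markers (-0.78, 0.00118, and adjusted p = 0.751 with an estimated correlation) were lower on the same arrays. The cholesterol synthesis list was slightly higher (0.09, 0.0448, and adjusted p = 0.687 with an estimated correlation). Against the oil arrays of the other times the muscle markers turned, to higher at 16 h with progesterone (0.34, adjusted p = 0.0117), and cholesterol synthesis was not called (-0.02, adjusted p = 0.791). The basal list stayed higher there (0.27, adjusted p = 1.85e-05), and mitosis (-0.33, 0.000338), replication (-0.20, 0.0188) and lymphocyte markers (-0.22, 0.000303) stayed lower. The 28 h oil arrays, included there, scored highest of the oil groups on the lists that stayed lower. The mitosis score, the mean log2 deviation of the members from their mean over all arrays, was -0.36 at 16 h with progesterone. In oil it was -0.25, 0.249 and -0.226 at 4, 28 and 76 h. Replication read -0.19 against -0.14, 0.156 and -0.152, and lymphocyte markers -0.0838 against 0.151, 0.358 and -0.00816. How far these falls rest on the 28 h oil arrays was not tested.

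The direction of the 38 calls was 13 up and 25 down, 8 up and 26 down with arrays centred on their medians, and 15 up and 19 down with quantile normalization. The count rested on single arrays more than at any other time. It was 1843 without progesterone replicate 1, 8 without oil replicate 2, 9 without progesterone replicate 2, 16 without progesterone replicate 3, 18 without oil replicate 3 and 20 without oil replicate 1. Arrays of other times moved it as well, to 23 without oil 4 h replicate 1 or progesterone 76 h replicate 2, to 24 without oil 28 h replicate 1, oil 76 h replicate 1 or oil 76 h replicate 2, and to 25 without oil 28 h replicate 2 or progesterone 76 h replicate 1. Of the 24 genes named as called at 16 h, 6 (Wnt4, Upk3a, Tspan1, Pgr, Ccn2 and Dnajc12) kept the call without any one array of that time. The call was lost by 18 genes without oil replicate 2, by 17 without progesterone replicate 2, by 14 without progesterone replicate 3, by 13 without oil replicate 3 and by 11 without oil replicate 1, at adjusted p up to 0.457.

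At 28 h, 17 of 24 genes of the connective tissue matrix and 4 of 20 basal markers were called higher with progesterone, and the caseins Csn2 and Csn1s2a, the immunoglobulin transcript Igk and 5 of 35 mitosis genes lower. With an estimated correlation the basal (adjusted p = 0.133) and mitosis lists (0.19) were not called, and against the oil arrays of the other times the matrix (-0.08) and mitosis lists (-0.18) were not. The matrix proteoglycan gene Vcan rose from 56.3 ± 23.2 to 216 ± 37.1, a log2 change of 2.01 ± 0.23 (adjusted p = 1.58e-05), and Krt17 from 23.1 ± 4.14 to 151 ± 56.0. Both means in oil lay under the array median. Rises followed for Cacna1g (2.02), Crispld1 (2.00), the matrix protease Adamts4 (1.95), Spon2 (1.91), the basal keratin gene Krt15 (1.78), the immediate early gene Egr2 (1.74), Akr1c18 (1.67), whose product inactivates progesterone, and the protease inhibitor Timp1 (1.58). The caseins fell, Csn1s2a from 352 ± 296 to 35.6 ± 23.4 (-3.04) and Csn2 from 660 ± 496 to 101 ± 45.8 (-2.47, adjusted p = 0.00343). Falls followed for the immunoglobulin kappa transcript Igk (-2.18), Ccn2 (-1.88), Upk3a (-1.76), Clca3a2 (-1.65), the transcription factor Foxi1 (-1.62), the protease Tmprss2 (-1.60), the plasma cell gene Mzb1 (-1.37) and Eaf2 (-1.36). Id4, an inhibitor of DNA binding, rose from 208 ± 27.2 to 601 ± 131 (2.86-fold, adjusted p = 9.28e-07). Wnt4 rose by 1.27, cyclin D1 (Ccnd1) by 0.57 and Wnt2 by 1.49, while Pgr stood at 178 ± 67.2 against 426 ± 19.4 in oil, a fall of -1.33. Tnfsf11 (0.37), Elf5 (-0.88, adjusted p = 0.0882), Esr1 (0.09) and Fkbp5 (-0.51) did not pass.

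Most of these 28 h differences did not hold against other controls. Of the 313 genes called, 44, or 14.1%, were called again in the same direction against the oil arrays of the other 3 times, whereas 22 of 23 (95.7%) were at 4 h, 32 of 38 (84.2%) at 16 h and 1879 of 2195 (85.6%) at 76 h. The median size of the called changes was 0.72 against the 28 h oil arrays and 0.10, in the same direction, against the others. For 227 of the 313 genes the 28 h oil arrays themselves differed from the other oil arrays. Against those other arrays, Csn2 was higher and not lower at 28 h with progesterone (3.51, adjusted p = 2.55e-05). Csn1s2a did not pass there (1.84, adjusted p = 0.0568), nor did Akr1c18 (-0.48, 0.222), Fn1 (-0.19, 0.536), Lum (-0.02, 0.965) and Mrc1 (-0.28, 0.315). The comparison with other controls was added after the data had been examined.

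The matrix list led the lists at 28 h. Of its 24 members, 17 rose over all genes and 21 rose when adjusted over the list alone, among them Fn1 (1.12), Loxl1 (0.95) and Lum (0.89), with a median of 0.49 (adjusted p = 3.55e-34, and adjusted p = 0.0189 with an estimated correlation). Its median against the other oil arrays was -0.08 (adjusted p = 0.401). The EGF-family and WNT list was higher (0.27, 1.27e-05, and adjusted p = 0.0373 with an estimated correlation), with Wnt4 and Wnt2 called and 5 members up when adjusted over the list alone. The basal list was higher (0.27, 1.97e-06, and adjusted p = 0.133 with an estimated correlation), with 4 of 20 members called, and 7 when adjusted over the list alone. Immediate early genes (0.25, 0.000363, and adjusted p = 0.133 with an estimated correlation) had Egr2, Egr1 (1.05) and Ier3 (0.55) called, and 6 of 18 up when adjusted over the list alone. Macrophage markers were higher (0.27, 3.39e-05, and adjusted p = 0.223 with an estimated correlation), with Mrc1 (0.72) and Fcgr3 (0.40) called, and 6 of 21 when adjusted over the list alone, but against the other oil arrays the list was lower (-0.27, adjusted p = 7.05e-05). The mitosis list fell to a median of -0.61 (adjusted p = 1.01e-17, and adjusted p = 0.19 with an estimated correlation). Of its 35 members 5 fell over all genes, among them Ncapg (-1.07), Mki67 (-0.95), Ube2c (-0.88) and Nek2 (-0.86), and 24 fell and 1 rose when adjusted over the list alone. Against the other oil arrays the mitosis list was not called (-0.18, adjusted p = 0.112). The EGF-family and WNT (0.19, 0.000601), basal (0.14, 6.99e-07) and immediate early lists (0.175, 4.54e-06) stayed higher there. The milk list was not called at 28 h (median 0.04, adjusted p = 0.302), with 2 of 13 members down, and 1 up and 3 down when adjusted over the list alone.

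Lists lower at 28 h with at most 1 member called over all genes were the replication genes (-0.20, 6.68e-05, and adjusted p = 0.455 with an estimated correlation), the lymphocyte markers (-0.32, 9.33e-09, and adjusted p = 0.246 with an estimated correlation), of which Jchain fell by 0.88 (log2 -0.88) and 6 fell when adjusted over the list alone, the clock genes (-0.41, 0.00368, and adjusted p = 0.19 with an estimated correlation), of which Tef fell (-0.50) and 3 rose and 10 fell when adjusted over the list alone, the interferon response (-0.08, 0.0448, and adjusted p = 0.741 with an estimated correlation) and the unfolded protein response (-0.07, 0.0483, and adjusted p = 0.678 with an estimated correlation). The steroid response list was lower (-0.11, 0.0453, and adjusted p = 0.537 with an estimated correlation), with 1 member up, Lcn2 (0.63), and 2 down, Tsc22d3 (-0.84) and Ddit4 (-0.79), and 2 up and 3 down when adjusted over the list alone. Of the 18 progesterone-responsive genes 3 rose and 2 fell, Pgr and Cited1 (-1.05), and 4 rose and 4 fell when adjusted over the list alone, but the list was not called (adjusted p = 0.442). Cholesterol synthesis was higher (0.25, 0.00426, and adjusted p = 0.425 with an estimated correlation), with Hmgcs1 (0.49) called. Skeletal muscle markers, none of them called alone, were higher at 28 h with progesterone (median 0.78, adjusted p = 3.08e-05, and adjusted p = 0.687 with an estimated correlation), the opposite of the other times, and lower against the other oil arrays (-0.45, adjusted p = 0.019). Against those arrays, by camera with the preset correlation alone, the replication list turned to slightly higher at 28 h (0.05, adjusted p = 0.0207) and the interferon response stayed lower (-0.21, 0.000226). Tef (0.00187, adjusted p = 0.996) and Jchain (-0.12, 0.793) were not called there. The lymphocyte (-0.11, 0.439), clock (-0.12, 0.783), unfolded protein (-0.03, 0.915), steroid (-0.10, 0.271) and cholesterol lists (-0.07, 0.894) were not called either. Without progesterone replicate 1 the count at 28 h was 140, and without oil replicate 2 it was 202. Of the 45 genes named as called, 26 kept the call without any one array of that time. The call was lost by 17 genes without progesterone replicate 1, by 12 without oil replicate 2, by 9 (Csn2 among them) without oil replicate 1, by 7 without progesterone replicate 3, by 6 without oil replicate 3 and by 2 without progesterone replicate 2, at adjusted p up to 0.409. Ncapg, Nek2 and Tef each lost it without 5 of the 6 arrays.

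At 76 h, 23 of 25 luminal epithelium markers and 33 of 35 mitosis genes were called higher with progesterone. Of 21 genes of fatty acid and triglyceride synthesis 16 were called lower. By camera with an estimated correlation the luminal list was called (adjusted p = 0.0373). The mitosis (0.133), replication (0.165), fatty acid (0.133) and cholesterol synthesis lists (0.133) were not. Tnfsf11, which encodes the paracrine signal RANKL, rose from 44.5 ± 7.39 to 360 ± 1.66 (mean ± SD, n = 3 arrays), a log2 change of 3.03 ± 0.29 with an adjusted p of 8.04e-08. Id4 rose from 241 ± 17.5 to 1600 ± 140 (2.73), the alveolar transcription factor Elf5 from 156 ± 47.2 to 778 ± 66.2 (2.36), Wnt4 from 68.7 ± 21.4 to 310 ± 35.2 (2.22) and Ccnd1 from 606 ± 33.1 to 1490 ± 169 (1.29). Pgr did not differ, at 279 ± 43.2 in oil and 279 ± 29.7 with progesterone (adjusted p = 0.993), while against the oil arrays of the other times it read -0.69 at 76 h (adjusted p = 0.0029). Esr1 (0.23), Csn2 (0.25, intensities under 10 in both groups) and Fkbp5 (0.39) did not pass either. The largest rises were those of Serpinb11 (from 15.3 ± 7.25 to 374 ± 93.0, or 26-fold), Lrrc15 (3.85), the defensin Defb1 (3.74), keratocan, Kera (3.67, from values near the floor), Acot1 (3.57), the WNT enhancer Rspo1 (3.52), Krt15 (3.26), the retinoic acid binding protein Crabp1 (3.26), the laminin Lama1 (3.21) and Bex1 (3.13). In oil, Serpinb11, Rspo1 (29.7 ± 6.23) and Tnfsf11 also lay under the array median, where a fold change is imprecise. The largest falls were those of Angptl8 (-2.23), a regulator of lipoprotein lipase, the potassium channel Kcnj6 (-2.14), Gap43 (-2.08), Maff (-1.72), Stmnd1 (-1.67), Ttc25 (-1.66), Mtarc1 (-1.65), butyrophilin, Btn1a1 (-1.62), and 2 genes of glycogen metabolism, Ppp1r3b (-1.62) and Gys2 (-1.62). Of the 2195 genes called, 395 changed at least 2-fold, and at 5522 of all genes (44.7%) the 3 arrays of one group lay beyond those of the other, where chance gives 10%. The calls were 1368 higher and 827 lower, and with quantile normalization 1298 higher and 1146 lower.

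**Figure D2:**
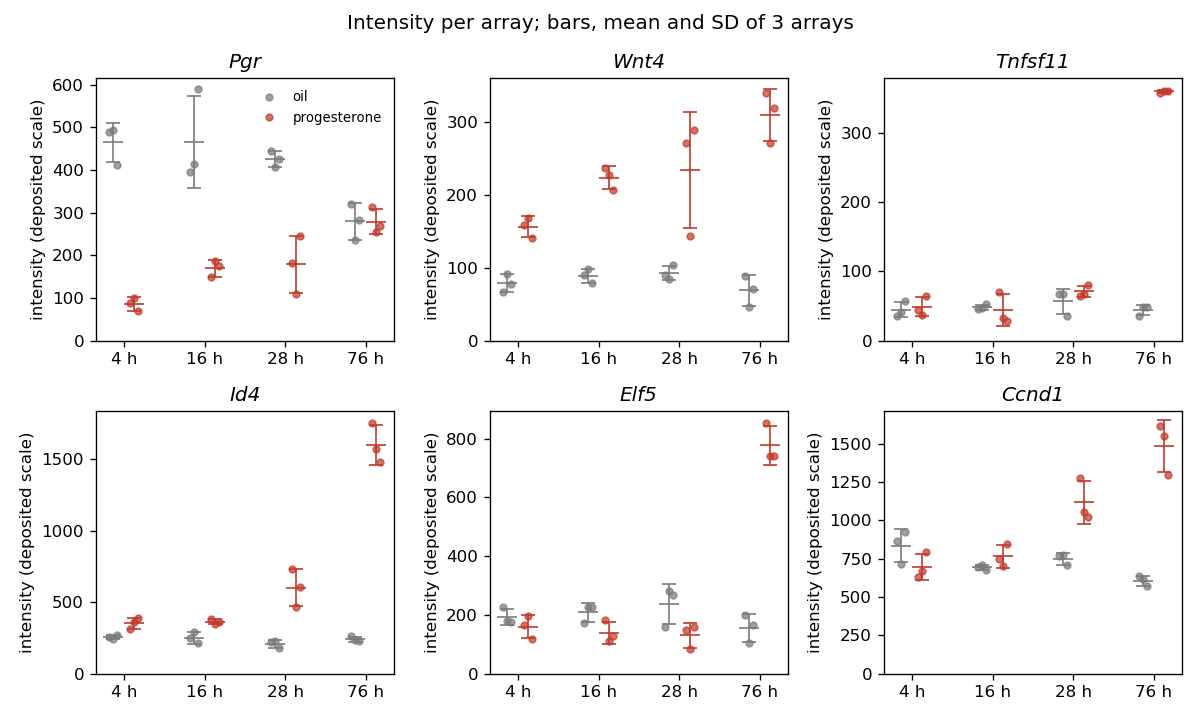
Intensity of 6 genes on each array (points), with the mean and SD of the 3 arrays of each group (bars), for oil (grey) and progesterone (red) at 4, 16, 28 and 76 h on a linear axis. Pgr is low with progesterone up to 28 h and at 279 in both groups at 76 h, and Tnfsf11 and Elf5 were called at 76 h, at 360 and 778, and at no other time.

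Epithelial genes rose across the lists at 76 h. Of 25 luminal markers 23 rose, both over all genes and adjusted over the list alone, among them the transcription factors Ehf (2.66) and Tfap2c (2.48), the splicing factor Esrp1 (2.47) and claudin 7, Cldn7 (2.07), with a median of 1.27 (adjusted p = 1.31e-24, and adjusted p = 0.0373 with an estimated correlation). Of 20 basal markers 14 rose over all genes, and 17 rose and 1 fell when adjusted over the list alone, among them Trp63 (2.65), Col17a1 (2.29) and Krt17 (2.07), with a median of 0.95 (adjusted p = 2.29e-13, and adjusted p = 0.0251 with an estimated correlation). Of the 35 mitosis genes 33 rose, and 33 when adjusted over the list alone, with Ccnb2 at 672 ± 186 against 161 ± 35.5 and Cdk1 at 909 ± 214 against 223 ± 16.7, and with Ttk (2.03) and Bub1 (1.90) among the others (median 1.36, adjusted p = 1.31e-24, and adjusted p = 0.133 with an estimated correlation). Of the 31 replication genes 21 rose, and 24 when adjusted over the list alone, among them Uhrf1 (from 102 ± 20.3 to 285 ± 36.0), Dtl (1.41), Mcm6 (1.29) and Tk1 (1.29), with a median of 0.63 (adjusted p = 9.78e-12, and adjusted p = 0.165 with an estimated correlation). Ribosome biogenesis had 8 of 25 members up, 10 when adjusted over the list alone, with Myc (0.96), nucleolin, Ncl (0.60), Npm1 (0.53) and Gar1 (0.47) among them (median 0.28, adjusted p = 9.87e-05, and adjusted p = 0.322 with an estimated correlation). Against the other oil arrays its median was 0.15 (adjusted p = 0.0207).

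Of the 18 progesterone-responsive genes 9 rose and 1 fell over all genes, and 10 rose and 2 fell when adjusted over the list alone (median 0.53, adjusted p = 2.28e-07, and adjusted p = 0.0554 with an estimated correlation). In the EGF-family and WNT list 8 of 15 rose, Wnt5b (1.41) and Wnt2 (1.07) besides Wnt4 and Rspo1, against 9 up and 1 down when adjusted over the list alone (median 0.49, adjusted p = 0.000143, and adjusted p = 0.0686 with an estimated correlation). The RANK and NF-kB list was not called (adjusted p = 0.697) although its member Tnfsf11 rose, and Traf1 fell (-0.49). The list of milk proteins and milk fat secretion went both ways, 4 up and 5 down of 13, and 5 and 5 when adjusted over the list alone. Wfdc18 rose from 1030 ± 161 to 5170 ± 46.8 and Aldoc by 1.48, while Lalba (-1.54) and Btn1a1 fell (list adjusted p = 0.57). The steroid response list was not called (adjusted p = 0.583), with Mt2 (1.23), the cell cycle inhibitor Cdkn1c (0.98) and Lcn2 (0.85) up and Dusp1 down (-0.79). It had 3 members up and 4 down, and the same numbers when adjusted over the list alone. Immediate early genes had 5 up and 2 down of 18, Egr2 (2.06), Ier3 (0.89) and Egr1 (0.86) among them, 8 up and 3 down when adjusted over the list alone, and no call as a list (adjusted p = 0.57).

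Most genes of lipid synthesis and a part of the adipocyte markers fell at 76 h. Of 21 genes of fatty acid and triglyceride synthesis 16 fell, 17 when adjusted over the list alone, with Acss2 at 1140 ± 139 against 2680 ± 371 and the elongase Elovl6 at 2600 ± 279 against 5680 ± 464, besides Pnpla3 (-1.47) and the carbohydrate-responsive transcription factor Mlxipl (-0.93) (median -0.52, adjusted p = 2.29e-13, and adjusted p = 0.133 with an estimated correlation). Of 17 cholesterol synthesis genes 12 fell, 13 when adjusted over the list alone, among them Sc5d (-0.99), Idi1 (-0.95), Cyp51 (-0.87) and Fdps (-0.80), with a median of -0.58 (adjusted p = 1.7e-07, and adjusted p = 0.133 with an estimated correlation). Against the other oil arrays the cholesterol median was -0.29 (adjusted p = 0.0415), and in the 76 h oil arrays the list lay above the other oil arrays (0.30, 5 members called, adjusted p = 5e-07, and adjusted p = 0.442 with an estimated correlation). White adipocyte markers fell less, 7 of 19 over all genes and 11 when adjusted over the list alone, with the glucose transporter Slc2a4 (-0.88), Lpin1 (-0.81), Adig (-0.72) and Gpd1 (-0.47) among them (median -0.28, adjusted p = 6.46e-07, and adjusted p = 0.183 with an estimated correlation). Of 8 brown adipocyte markers 4 fell, 6 when adjusted over the list alone, Cidea (-1.32), Cox8b (from 3000 ± 353 to 1280 ± 202), Cox7a1 (-0.99) and Prdm16 (-0.61) (median -0.80, adjusted p = 0.000633, and adjusted p = 0.223 with an estimated correlation).

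Markers of the other cell types moved apart at 76 h. Of 24 fibroblast and matrix genes 17 rose, and 17 rose and 1 fell when adjusted over the list alone, among them Timp1 (from 106 ± 16.4 to 469 ± 90.1), tenascin C, Tnc (1.48), Loxl1 (0.89) and Col5a2 (0.88), with a median of 0.54 (adjusted p = 1.57e-09, and adjusted p = 0.183 with an estimated correlation). Of 15 endothelial markers 7 fell on either count, adjusted over the list alone or over all genes, Cldn5 (-0.70), Robo4 (-0.54), Cdh5 (-0.47) and Ptprb (-0.42) (median -0.35, adjusted p = 2.07e-05, and adjusted p = 0.19 with an estimated correlation). Of 20 lymphocyte markers 10 fell, 17 when adjusted over the list alone, Cd79b (-0.59), Cd8a (-0.59), Blk (-0.55) and Ms4a1 (-0.52) (median -0.47, adjusted p = 3.56e-08, and adjusted p = 0.255 with an estimated correlation). The macrophage list was not called (median 0.01, adjusted p = 0.54), with Cd14 up (0.47) and Ctss down (-0.20). Another probe set of Cd8a read 0.30, which is the opposite direction. Skeletal muscle markers were lower (-0.43, 0.0319, and adjusted p = 0.876 with an estimated correlation, and -0.94 against the other oil arrays), and so was the interferon response (-0.18, 0.0185, and adjusted p = 0.687 with an estimated correlation), of which Oasl1 fell (-0.54). In the nerve list, which was not called, Sox10 rose from 187 ± 23.1 to 557 ± 103 and Pmp22 fell (-0.37). Sox10 is also known from mammary epithelium. The clock list was not called either, with Arntl (-0.66) and Clock (-0.31) down and Wee1 (1.24) and Hlf (0.58) up. Against the other oil arrays Arntl read 0.51, Clock 0.19 and Hlf -0.38. The unfolded protein response was not called (adjusted p = 0.622), with Dnajb9 down (-0.45) and Pdia6 up (0.33). Another probe set of Clock read 0.18, which was not called. The 76 h count was 1383 without progesterone replicate 1. Of the 96 genes named as called at 76 h, 76 kept the call without any one array of that time. The call was lost by 15 genes without oil replicate 2 or progesterone replicate 1, by 12 without oil replicate 3, by 11 without progesterone replicate 3 and by 10 without oil replicate 1 or progesterone replicate 2, at adjusted p up to 0.229. Kcnj6, Stmnd1, Egr1, Cldn5, Cd79b, Ms4a1, Arntl, Hlf and Clock were among those 20 genes.

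**Figure D3:**
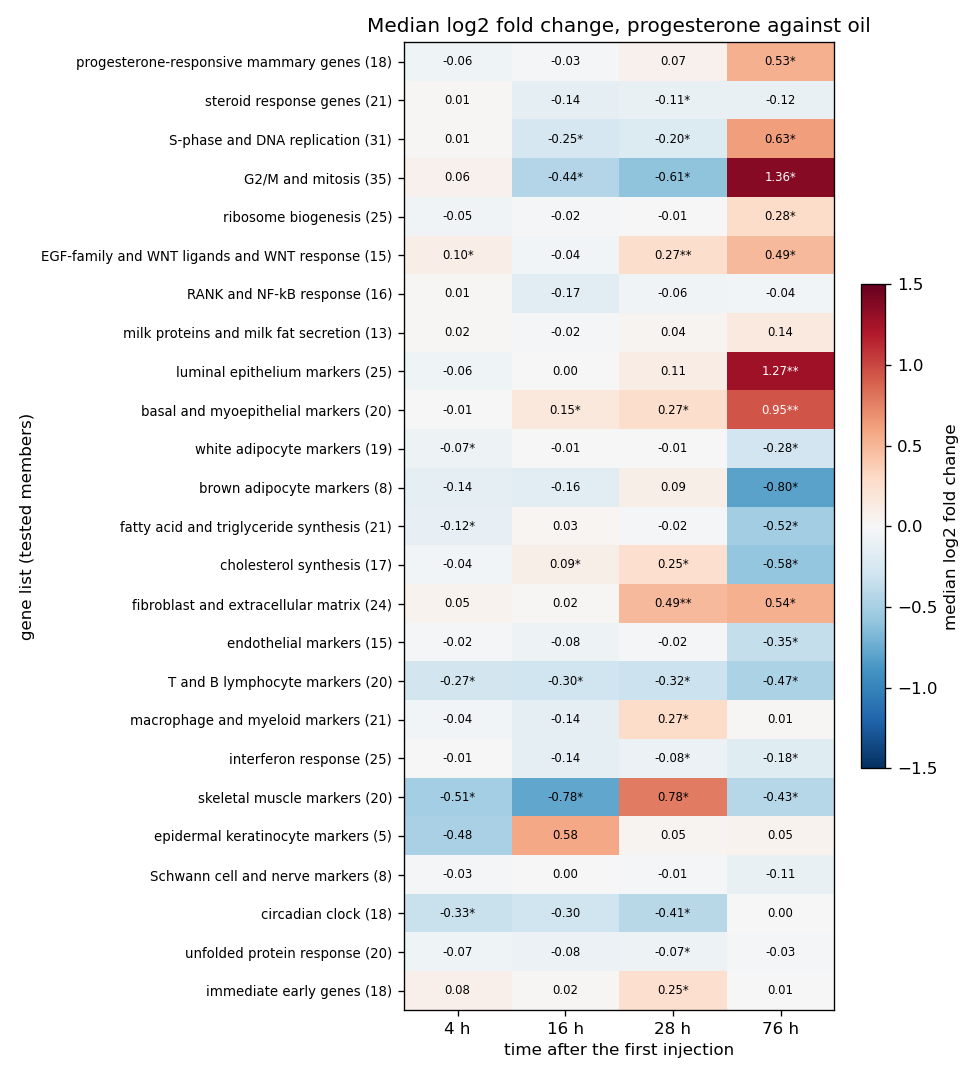
Median log2 fold change, progesterone against oil, of the tested members of 25 gene lists (vertical axis, number of members in brackets) at 4, 16, 28 and 76 h (horizontal axis), as colour and number. One star marks a call by camera with a preset correlation, and a second star a call that held with an estimated correlation, as for the luminal list at 76 h (1.27).

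Across the 25 lists and 4 times, 42 of 100 tests were called with the preset correlation and 4 with the estimated one. These 4 were the matrix and the EGF-family and WNT lists at 28 h and the luminal and basal lists at 76 h. The list of epidermal keratinocyte markers, with 5 members, was called at no time (adjusted p from 0.0592 at 16 h to 0.878 at 76 h).

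Averaged over the 4 times, 1539 genes differed between progesterone and oil, 720 of them higher and 819 lower. With arrays centred on their medians 584 were higher and 1051 lower, and with quantile normalization 868 higher and 698 lower. Which direction prevailed thus depended on the scaling. The average leaned on the last time, since 614 genes were called without 76 h. The same gene was called in the same direction at 2 or more times in 154 cases and at 3 or more in 20. Called at all 4 times were Mboat1 and Tceal9, always higher, and Ly6d, always lower. Pgr and Slc7a2 were lower at 4, 16 and 28 h. Slc12a2 was lower at these times and higher at 76 h. The basal genes Krt5, Krt17 and Acta2, with Wnt4, Cacna1g and Tfap2b, were higher at 16, 28 and 76 h. Between 28 and 76 h, 118 genes were higher at both where 26.6 are expected of independent lists (Fisher's exact test, adjusted p = 3.6e-49), and 15 were lower at both where 4.89 are expected (adjusted p = 9.61e-05). Among the 118 were Fn1, at -0.19 at 28 h against the other oil arrays, and Col14a1, low in the 28 h oil arrays themselves (-1.16). Of all genes called at 28 h, 14.1% were called again against the other oil arrays, and the overlaps with 28 h were not recounted there. Between 16 and 28 h, 9 genes were higher at both (0.253 expected, adjusted p = 9.08e-13) and 15 lower at both (0.148 expected, adjusted p = 1.51e-27). Between 4 and 76 h, 10 genes were higher at both (1.77 expected, adjusted p = 1.53e-06) and Ly6d alone was lower at both (0.469 expected, adjusted p = 0.384). These comparisons share no arrays, but they share the estimate of each gene's spread, and genes are not independent replicates. Across all genes the log2 fold changes correlated with Pearson's r from 0.0885 (16 and 76 h) to 0.34 (16 and 28 h). Called in opposite directions at 28 and 76 h were 18 genes, among them Mki67, Ube2c, Ncapg, Nek2, Cited1, Upk3a, Tlcd4 and Slc12a2, lower at 28 h and higher at 76 h. Hmgcs1 and Ackr3 were higher at 28 h and lower at 76 h. Against the other oil arrays Upk3a (-1.74) and Cited1 (-0.94) were still lower at 28 h, while Mki67 (-0.29), Ube2c (-0.18), Ncapg (-0.34), Nek2 (0.0042) and Hmgcs1 (-0.00317) were not called. Ackr3 was low in the 28 h oil arrays themselves (-0.85). Without 28 h the overlap of 154 genes was 28, and without 76 h it was 30. The count of 154 was 353 without progesterone 16 h replicate 1, 262 without progesterone 4 h replicate 3, 236 without progesterone 28 h replicate 2 and 93 without progesterone 28 h replicate 1.

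The effect of progesterone itself differed between the times at 1238 genes (moderated F-test in limma). The 10 genes with the smallest p were Emid1, Col7a1, Id4, Irx3, Nxn, Rspo1, Col16a1, Gm266, Sdc1 and Ltf. For 9 of them the change was largest at 76 h and positive, for example Col7a1, a basement membrane collagen, at -0.19, 0.17, 0.51 and 2.52 in order of time, and the proteoglycan Sdc1 at 0.04, 0.27, 0.98 and 1.95. Emid1 reached 2.37 at 76 h, Irx3 1.81, Nxn 1.53, Col16a1 1.81 and Gm266 3.88 (from 25.4 in oil, under the array median). Ltf, lactoferrin, was the exception, at -0.09, 0.23, 0.20 and -1.32. The effect on Pgr differed too (adjusted p = 5.65e-05), by 2.46 between 4 and 76 h. In oil itself Pgr was lower at 76 h than at the other times (-0.695, limma adjusted p = 0.0314). Against the oil arrays of those times Pgr was lower at 76 h with progesterone as well (-0.69). How much of the 2.46 comes from the 76 h oil arrays was not tested. Between 4 and 16 h the effect differed at 1 gene (and at 1700 genes at an unadjusted p under 0.05), between 16 and 28 h at 26, between 28 and 76 h at 944 and between 16 and 76 h at 1375. The effect on the mitosis list differed between 28 and 76 h, with a median difference of 2.04 (adjusted p = 2.65e-39, and adjusted p = 0.0534 with an estimated correlation). At 28 h it was called lower against the oil arrays of that time (-0.61) and not called against the others (-0.18, adjusted p = 0.112). In the 28 h oil arrays the list itself lay higher than in the others (0.37, adjusted p = 4.87e-12, and adjusted p = 0.581 with an estimated correlation). Without 76 h the effect differed at 52 genes. The count was 2238 without progesterone 16 h replicate 1, 740 without progesterone 76 h replicate 1 and 787 without oil 76 h replicate 1.

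**Figure D4:**
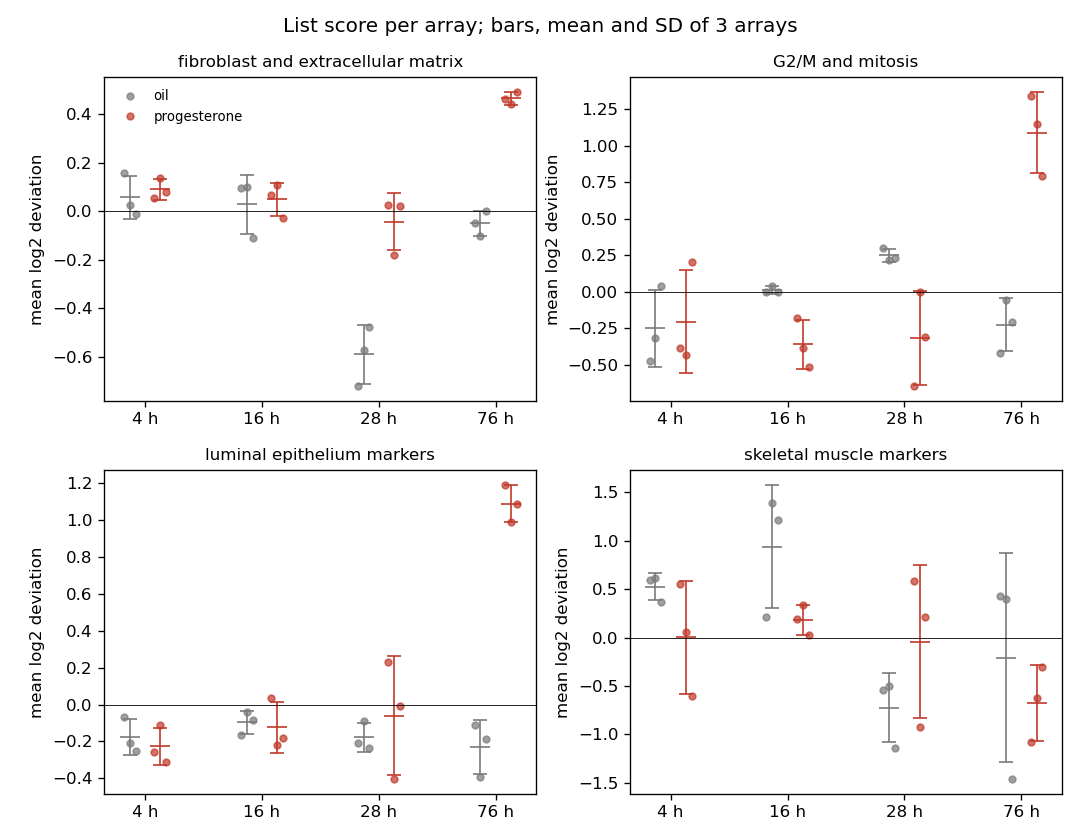
Mean log2 deviation of the members of 4 gene lists from their mean over all 24 arrays, on each array (points), with the mean and SD of 3 arrays (bars), for oil (grey) and progesterone (red) at 4, 16, 28 and 76 h. The matrix score of the 28 h oil arrays lies at -0.59 ± 0.122, below all other groups, and the muscle score spreads widely within groups.

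The oil arrays alone, which saw no hormone, measure what time, handling and tissue sampling do. Between the 4 oil groups 1506 genes differed (moderated F-test in limma), and the 28 h group stood furthest apart, with 939 genes against the other 3 groups, 185 higher and 754 lower. The other groups differed from the rest at 353 (4 h), 123 (16 h) and 369 genes (76 h). Csn2 read 660 ± 496 in oil at 28 h, with single arrays from 212 to 1190, and 8.53 ± 3.58, 8.03 ± 4.31 and 4.51 ± 1.95 at 4, 16 and 76 h (F-test adjusted p = 3.85e-08). The semaphorin Sema3c (750 ± 150 against 1260 to 1650 in the other groups), Efhd1 (-1.53 against the other oil groups), Akr1c18 (-2.15), Igfbp6 (-1.41), the chemokine receptor Ackr3 (-0.85), the WNT inhibitor Sfrp2 (-1.47), the chemokine Ccl24 (-1.72), Lrrc17 (-1.12) and the collagen Col14a1 (-1.16) were all low at 28 h. The matrix list was lower in oil at 28 h (median -0.55, 21 of 24 members called, adjusted p = 9.29e-31, and adjusted p = 0.0314 with an estimated correlation), and so were the macrophage markers (-0.42, 2.01e-10, and adjusted p = 0.22 with an estimated correlation) and the skeletal muscle markers (-1.20, 9.92e-09, and adjusted p = 0.581 with an estimated correlation). Muscle markers were higher in oil at 16 h (1.18, 2.01e-10, and adjusted p = 0.581 with an estimated correlation). The count of 1506 was 450 without the 28 h groups, 874 with a muscle score as covariate (both added after the data had been examined), 911 without oil 76 h replicate 1, 939 without oil 4 h replicate 1, 986 without oil 16 h replicate 2 and 988 without oil 28 h replicate 2.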

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

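Of the tests in this part, the comparison with other oil arrays and the tests of the muscle content, of the clock genes (both) and of cell content at 76 h (all 3) were chosen after the results had been seen. The test for a batch shared by all 28 h arrays, with its bound, was written before its value was seen, and the margin of 1 SE was chosen after.

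Against the oil arrays of the other times, 14.1% of the 313 genes called at 28 h were called again in the same direction, and 939 genes parted the 28 h oil arrays from the other oil arrays. Skeletal muscle content as the whole cause is argued against by the 65.5% of the genes (205) that stayed called with a muscle score as covariate, with a median change of 0.688 in place of 0.722. Over the 939 genes the progesterone 28 h arrays moved by 0.135 ± 0.0864 (SE) in the direction of the oil shift (median 0.533). This lies under the bound of 0.266 set in advance by more than 1 SE, but 2 SE would reach 0.308, above it. The genes were also picked by the shift of the 28 h oil arrays, which tends to enlarge that shift and so the bound. The test therefore does not decide on a processing batch shared by all 28 h arrays as the whole cause. A shared part stays open as well, since 85.3% of these genes moved the same way, and so does a biological difference, which was not tested. That the 28 h oil arrays stand apart is what the pattern itself shows, and it has no separate test.

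The oil 76 h arrays differed in clock genes from the oil 4 h and 28 h arrays, although 4, 28 and 76 h lie whole days apart. The 5 clock genes that peak with Arntl were higher by 1.05 and the 10 that peak with Dbp lower, by -0.909 (exact permutation p = 0.0119 each, the smallest that 84 splits can give). Opposite shifts argue against a difference in tissue content or RNA quality that moves all clock genes alike. Collection at another phase of the daily cycle may account for them, as a hypothesis found and tested on the same data, with the hour of collection not given in the sources used here. But the shifts were opposite with progesterone too, 0.659 and -0.564 at 4 h and 0.335 and -0.493 at 28 h, although the oil arrays of these nominal times read 0.0356 and -0.0102 at 4 h and -0.0356 and 0.0102 at 28 h, so that an effect on the clock at the same hour stays open.

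At 76 h with progesterone, 7 of 19 white adipocyte, 7 of 15 endothelial and 10 of 20 lymphocyte markers were called lower and 23 of 25 luminal markers higher, and of these lists only the luminal one was called with an estimated correlation (adjusted p = 0.183, 0.19, 0.255 and 0.0373). Dilution of all other cell types by epithelial RNA as the whole cause would lower them alike, but the fibroblast list moved by 0.805 ± 0.055 (SE) more than the white adipocyte list. A separate rise of matrix genes on top of dilution would give this as well, so that the difference does not decide on dilution of the lists that fell. These moved by -0.29 ± 0.0555 (white adipocyte), -0.356 ± 0.0727 (endothelial) and -0.464 ± 0.0918 (lymphocyte), and their dilution stays open. Loss of white adipocyte RNA as the whole cause of the lower fatty acid synthesis transcripts is argued against by a further difference, -0.267 ± 0.0608 beyond the white adipocyte markers, with 0 genes shared by the lists. Loss of brown adipocyte RNA is not argued against and stays open, since the synthesis list fell by no more than the 8 brown adipocyte markers (-0.557 and -0.729, a difference of 0.172 ± 0.142). Changes in the number of fibroblasts or epithelial cells, and in transcription within cells, stay open and were not tested.

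The arrays were also split in other ways, each time counting calls by limma. The 10 splits of 3 against 3 arrays are too few for a share under 0.05, the real count and the highest other being 23 and 155 at 4 h, 38 and 1828 at 16 h, 313 and 18 at 28 h, and 2195 and 0 at 76 h. At 4 and at 16 h, 2 of the 10 splits gave as many genes, the real one included, and at 28 and at 76 h 1 did. Splits with several times the real count, as at 4 and 16 h, point to a structure among the arrays, whose kind was not tested, and a single deviating array stays open, since the 16 h count was 1843 without progesterone replicate 1. Of 100 splits drawn at random, 1 (the real one) reached the mean effect over the times (1539, highest other 833) and the effect differing between times (1238 and 1140). The same held for the oil groups (1506 and 317) and the overlap between times (154 and 7). For the number of lists called 2 did (42, highest other 43), so that another split called more lists than the real one. The share was under 0.05 for each of these 5. It covers each result as pooled over the times, and no single time or list.

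Each result in this paragraph and the next is here because the effect of progesterone differed between the times. Of 175 genes named in the text, this held for 129 (moderated F-test in limma, adjusted p under 0.05), and the highest minus the lowest of the 4 log2 fold changes measures by how much. The 175 genes were named mostly for large changes at single times, or for the smallest p of this F-test or the oil F-test. That choice itself raises the share, and over all 12352 genes 1238 were called. Ranges that involve 28 h depend on the 28 h oil arrays. There, Csn2 read 5.98 and Akr1c18 -2.15 against the other oil arrays. From the widest down, the range was 4.61 for Serpinb11, 4.28 for Aldh3a1, 3.95 for Gm266, 3.85 for Defb1, 3.72 for Lrrc15, 3.71 for Rspo1, 3.69 for Lama1, 3.67 for Kera, 3.66 for Csn1s2a, 3.48 for Bex1, 3.29 for Tnfsf11 and 3.27 for Kcnj6. It was 3.26 for Upk3a, 3.24 for Elf5, 3.15 for Ehf, 3.11 for Crabp1, 3.10 for Tspan1, 3.06 for Krt15, 3.00 for B3gnt7, 2.95 for Angptl8, 2.88 for Ccnb2, 2.83 for Fgg, 2.83 for Trp63 and 2.78 for Col17a1. Next came 2.73 for Csn2, 2.71 for Bub1, 2.71 for Col7a1, 2.69 for Cdk1, 2.62 for Lalba, 2.61 for Emid1, 2.55 for Ttk, 2.54 for Ube2c, 2.54 for Cntnap2, 2.54 for Gap43, 2.50 for Vcan and 2.48 for Mki67. The range was then 2.46 for Krt17, 2.46 for Pgr, 2.40 for Esrp1, 2.40 for Acot1, 2.38 for Ncapg, 2.30 for Timp1, 2.29 for Id4, 2.29 for Tfap2c, 2.27 for Maff, 2.25 for Dtl, 2.21 for Cldn7 and 2.15 for Wfdc18. Further down it was 2.05 for Ppp1r3b, 2.04 for Nek2, 2.02 for Krt5, 2.00 for Crispld1, 1.99 for Irx3, 1.93 for Col16a1, 1.91 for Uhrf1, 1.91 for Sdc1, 1.90 for Wee1, 1.87 for Cacna1g, 1.85 for Ccn2 and 1.85 for Tnc. Then followed 1.84 for Tlcd4, 1.83 for Spon2, 1.83 for Cited1, 1.82 for Btn1a1, 1.79 for Aldoc, 1.75 for Tfap2b, 1.75 for Gys2, 1.69 for Rnf180, 1.67 for Sox10, 1.66 for Eaf2, 1.65 for Pnpla3 and 1.62 for Tmprss2. Narrower ranges were 1.61 for Mcm6, 1.61 for Cidea, 1.61 for Nxn, 1.60 for Akr1c18, 1.58 for Mtarc1, 1.56 for Egr2, 1.56 for Ltf, 1.55 for Ccnd1, 1.53 for Ccl24, 1.51 for Cox8b, 1.45 for Igfbp6 and 1.45 for Tk1. Lower values were 1.43 for Wnt5b, 1.37 for Ier3, 1.35 for Arntl, 1.33 for Slc12a2, 1.32 for Efhd1, 1.28 for Acss2, 1.28 for Hlf, 1.25 for Sc5d, 1.24 for Lmo4, 1.23 for Wnt2, 1.22 for Wnt4 and 1.20 for Dnajc12. Below these stood 1.15 for Fn1, 1.14 for Cdkn1c, 1.12 for Cyp51, 1.11 for Elovl6, 1.08 for Ackr3, 1.06 for Eppk1, 1.04 for Sfrp2, 1.02 for Loxl1, 0.99 for Col14a1, 0.97 for Fdps, 0.96 for Dusp1 and 0.95 for Lcn2. Next in order were 0.95 for Lrrc17, 0.94 for Myc, 0.93 for Sema3c, 0.92 for Lum, 0.90 for Hmgcs1, 0.89 for Col5a2, 0.88 for Slc2a4, 0.84 for Tpgs1, 0.81 for Ncl, 0.81 for Mrc1, 0.80 for Lpin1 and 0.75 for Tef. The last were 0.75 for Adig, 0.74 for Clock, 0.64 for Npm1, 0.63 for Dnajb9, 0.56 for Fcgr3, 0.55 for Sqstm1, 0.54 for Gpd1, 0.50 for Tceal9 and 0.42 for Acta2.

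The effect on a list differed between at least 1 pair of times for 22 lists by camera, and for 4 of them also with an estimated correlation (matrix, luminal, basal and progesterone-responsive genes). The values are median differences in log2 fold change, later minus earlier, for the pair with the smallest p. Between 4 and 28 h they were -0.22 for steroid response genes. Between 28 and 76 h they were 0.77 for S-phase and DNA replication, 2.04 for G2/M and mitosis, -0.90 for cholesterol synthesis and -0.996 for brown adipocyte markers. Between 4 and 76 h they were 1.08 for basal and myoepithelial markers, 0.80 for progesterone-responsive mammary genes, 0.33 for ribosome biogenesis, 0.43 for EGF-family and WNT ligands and WNT response, 1.37 for luminal epithelium markers and -0.17 for interferon response. Between 16 and 76 h they were -0.20 for white adipocyte markers, -0.62 for fatty acid and triglyceride synthesis, -0.28 for endothelial markers and -0.21 for T and B lymphocyte markers. Between 4 and 16 h they were 1.00 for epidermal keratinocyte markers. Between 16 and 28 h they were 0.47 for fibroblast and extracellular matrix, 0.38 for macrophage and myeloid markers, 1.55 for skeletal muscle markers, -0.0313 for milk proteins and milk fat secretion, -0.0452 for unfolded protein response and 0.21 for immediate early genes. The differences that involve 28 h were taken against the 28 h oil arrays, which stood apart from the other oil arrays. Against the oil arrays of the other times, which for 16 h include those of 28 h, the order turned for the matrix, macrophage and muscle lists. Their medians there were 0.23, 0.08 and 0.345 at 16 h and -0.08, -0.27 and -0.45 at 28 h. The steroid response medians there were -0.0995 at 4 h and -0.104 at 28 h. For the mitosis, replication, cholesterol and brown adipocyte lists the order of 28 and 76 h stayed. Their medians there were -0.18, 0.05, -0.07 and -0.12 at 28 h and 1.15, 0.46, -0.29 and -0.85 at 76 h. For 76 h the other oil arrays include those of 28 h, and the differences there were not tested.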

How the results depend on the processing

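Using other oil arrays as controls, the muscle covariate, leaving out 28 or 76 h and the overlap without single arrays were chosen after seeing the data. Counts stayed within 1.5 times the reported ones with both other filters, quantile normalization, centring, the higher floor, the pseudocount, the mean of a gene's probe sets and both other variance models. Where a count moved further, the cause was not tested, except that fewer arrays or times and stricter or looser thresholds change it by construction. The labels do not say that replicate numbers pair arrays. As a hint from the data, 6 of 12 pairs of the same number correlated above 0.1 (from -0.018 to 0.346), all 4 pairs of replicate 3 among them, and 7 of 12 progesterone arrays, not all, correlated best with the oil array of their own number, so that the numbers were not taken to pair the arrays. With a replicate block, 233 genes were called at 4 h, 83 at 16 h, 514 at 28 h, 1865 for the effect differing between times, and 326 in the overlap. Array weights (from 0.216 to 5.5) gave 2771, 7332, 1619 and 4827 genes at 4, 16, 28 and 76 h, 5674 for the mean, 8195 for the effect differing and 8286 between oil groups. Testing all probe sets singly gave 36 at 4 h and 2697 between oil groups. An adjusted p under 0.10 gave 105, 67 and 475 at 4, 16 and 28 h, 1864 for the effect differing, 2601 between oil groups and 271 in the overlap, and a 1.5-fold minimum 206 at 28 h, 985 at 76 h and 161 for the mean. Fits to the 6 arrays of a time gave 11, 16, 76 and 3533, and other oil arrays as controls 804, 559, 108 and 4028. Of the lists, 4 were called with an estimated correlation and 22 by fry. With a muscle covariate 874 genes differed between oil groups. Leaving out 28 h gave 450 between oil groups and 28 in the overlap, and leaving out 76 h gave 614 for the mean, 52 for the effect differing and 30 in the overlap. Without single arrays the counts ran from 12 to 477 at 4 h, 8 to 1843 at 16 h, 140 to 459 at 28 h, 1383 to 2392 at 76 h, 1219 to 2086 for the mean, 740 to 2238 for the effect differing, 911 to 1942 between oil groups, 36 to 50 for lists and 93 to 353 for the overlap.

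For named genes, 206 results were recomputed. Other settings left direction and call as they were in 2714 cases, ended the call in 202, made one in 19, turned an uncalled sign in 23 and reversed 20. Against other oil arrays the reversals were Csn2 at 4 h (-1.85), 28 h (3.51) and 76 h (-1.97), Akr1c18 (-0.48), Csn1s2a (1.84), Nek2 (0.0042), Hmgcs1 (-0.00317), Fn1 (-0.19), Lum (-0.0156), Mrc1 (-0.28), Fcgr3 (-0.30) and Tef (0.00187) at 28 h, and Arntl (0.51), Hlf (-0.38), Clock (0.19) and Pgr (-0.69) at 76 h. At 4, 16 and 76 h the other oil arrays include those of 28 h, in which Csn2 read 660 against 8.53, 8.03 and 4.51 at 4, 16 and 76 h, so that its values of -1.85 and -1.97 are not read as changes with progesterone. Other probe sets of a gene reversed Mboat1 (-0.34) and Tlcd4 (0.20) at 16 h and Cd8a (0.30) and Clock (0.18) at 76 h, and the cause was not tested. Leaving out single arrays kept 992 results, ended the call in 230, made one in 4, turned an uncalled sign in 10 and reversed 0. Signal near background limits genes under the array median.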

Other observations

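The transcripts Igk and Jchain were higher in the oil arrays of 28 h, with no hormone given, than in the other oil arrays. The immunoglobulin kappa transcript Igk read 1850 ± 381 there (n = 3 arrays), a log2 difference of 1.80 ± 0.39 (SE) from the other oil arrays (adjusted p = 0.00427), and Jchain read 6900 ± 601 (0.76, adjusted p = 0.0071). Mki67, a marker of dividing cells, was higher as well (0.65 ± 0.17, adjusted p = 0.0201). These genes were looked at after their values had been seen, and no explanation was tested.

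Some clock genes of the oil arrays, picked after their values had been seen, read nearly the same at 4 and 28 h and differently at 16 and 76 h, and others did not. In order of time, Dbp read 2580 ± 520, 1420 ± 542, 2570 ± 81.4 and 724 ± 219 (F-test in limma, adjusted p = 9.7e-05), and Per3 327 ± 33.4, 211 ± 49.2, 327 ± 14.4 and 167 ± 29.5 (adjusted p = 0.000135). Arntl went the other way, at 89.8 ± 6.75, 155 ± 39.4, 78.9 ± 5.51 and 233 ± 41.7 (adjusted p = 7.71e-05), and so did Npas2, near the floor at 4 and 28 h (13.3 ± 4.6 and 10.5 ± 6.37, against 58.3 ± 10.5 at 76 h). Per2 did not follow this order, at 159 ± 22.7, 148 ± 36.3, 237 ± 25.4 and 146 ± 4.95 (adjusted p = 0.0661), nor did Nr1d1, at 756 ± 265, 275 ± 15.8, 487 ± 236 and 263 ± 20.4 (adjusted p = 0.0108). The mean shift of the genes that peak with Arntl, against oil at 4 and 28 h, was 0.727 in oil at 16 h, and with progesterone 0.659 at 4 h, 0.823 at 16 h, 0.335 at 28 h and 0.909 at 76 h. That of the genes that peak with Dbp was -0.546 in oil at 16 h, and with progesterone -0.564, -0.873, -0.493 and -0.829 in order of time. Skeletal muscle content varied between arrays of 1 group, the muscle score of the oil 76 h arrays running from -1.46 to 0.431.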
